A study of Mus musculus with 12 samples.

How the data were processed

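The data are 12 RNA-seq libraries of ectoplacental cones, the trophoblast tissue at the tip of the mouse conceptus, dissected at embryonic day 7.5. Per the labels, each library came from 10 ng of total RNA (SMARTer stranded kit) read as paired ends of 100 bp. There are 4 groups of 3 libraries. In the Ring1 experiment, all embryos lacked Ring1A, and tamoxifen given to the mother at embryonic day 5.5 removed Ring1B (the gene Rnf2) in the ΔRing1A/B group but not in the controls. In the Eed experiment, embryos made by in vitro fertilization were exposed at embryonic day 3.5 to 4-hydroxytamoxifen, over 10 hours, which removed Eed in the ΔEed group but not in the controls. Per the labels, the Ring1 experiment was sequenced on an Illumina HiSeq and the Eed experiment on a NovaSeq, so experiment, platform, embryo handling and time of deletion cannot be told apart, and each mutant was compared with its own controls. Sex is labelled, as female, for the Ring1 experiment alone. The labels give no litter and do not state whether each library came from a separate embryo, so p-values measure the spread between these libraries.

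The deposited table lists 22720 genes with coordinates. FPKM values (fragments scaled to transcript length and library size) were deposited by the authors, and Cufflinks 2.2.1, Cuffdiff and the mouse build mm9 are named in the submitters' processing notes. The aligner, the variant list behind the allele calls and the scaling between libraries are not given in the sources used here. Counts of allele-assigned reads per gene were deposited by the authors with no normalization. The fraction of those reads that came from the paternal allele was deposited by the authors for X-linked genes with at least 10 reads in a library. Fraction times reads was a whole number, within 0.001, for 100.0% of the values, and these products were used as paternal read counts. Allele-assigned reads lay on chromosome X alone, on 281 genes between 86649187 and 166428729 (mm9). Per the labels, the strain of the Ring1 experiment carries a part of the X from MSM mice, and the strain is not labelled for the Eed experiment. Tsix and Tmsb4x had 10 or more reads but no deposited fraction and were left out of the allelic tests. The table holds 951 X-linked genes and 0 Y-linked genes. Starts in the table count from 0: at 9533 of the 21415 symbols shared with RefSeq the end minus the start equals the RefSeq gene length, against 622 for that difference plus 1. Printed starts have 1 added. The reference annotation supplied for this organism is of another build, and none of its coordinates were used.

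Allele-assigned reads per library ranged from 65337 to 77909 in the Ring1 controls, 78203 to 111969 in ΔRing1A/B, 103255 to 119556 in the Eed controls and 144353 to 173530 in ΔEed. Total fragments behind the FPKM values are unknown. From the steps of low FPKM values, relative depth ranged from 1 to 1.3 in the Ring1 controls, 1.07 to 1.43 in ΔRing1A/B, 1.75 to 2.11 in the Eed controls and 1.76 to 2.41 in ΔEed, as multiples of the first Ring1 control. All 12 pairs of replicate libraries differed by more than counting noise in their allelic reads (smallest chi-square per degree of freedom 15.1), and none had identical FPKM values. No library thus appears to be deposited again as another of its group, and each was counted once. Libraries of different groups were not compared in this way. This does not show that the libraries came from separate RNA, since reads are not independent molecules.

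For expression, limma 3.58.1 in R 4.3.3 (eBayes with trend and robust) was fitted to log2(FPKM + 1) for genes with a mean FPKM of at least 1 over the 6 libraries of an experiment, so genes low in both groups were not tested, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes, and errors of fold changes are standard errors (SE). The difference between the effects of both mutants was tested as an interaction over the 12 libraries. The X-linked shift is the mean log2 change of X-linked genes minus that of autosomal genes, tested with camera at a preset correlation of 0.01, again with an estimated correlation, and by an exact two-sided permutation test of the library values, which cannot go below 0.1 with 3 against 3. X-linked means were also set against 10000 random autosomal lists matched on mean expression. Gene lists fixed before the data were examined were tested with camera and fry, with adjustment over the lists of 3 or more tested members. Fry asks whether the members move, on balance, one way and does not compare them with other genes. The lists cover PRC1 and PRC2 subunits, the X inactivation centre, known escapees, X-linked housekeeping genes, the Rhox cluster, Y-linked genes, Hox genes, developmental regulators bound by Polycomb, cell cycle inhibitors and p53 targets, germline genes, 3 groups of imprinted genes, dissection stress, proliferation, and markers of trophoblast stem cells, ectoplacental cone, giant cells, labyrinth, decidua, erythroid cells, endoderm, epiblast, leukocytes and endothelium.

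For allelic counts, paternal shares were computed per library over genes with at least 10 allelic reads in each of the 6 libraries of an experiment, with Xist kept and left out, and compared by exact two-sided permutation tests. Per gene, edgeR 4.0.16 (quasi-likelihood) tested the interaction of allele and genotype with the library as a block. Shares of single libraries carry 95% Wilson intervals. Intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

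Named genes followed a rule set before the data were examined: the targeted genes, the 8 largest autosomal rises and falls, the 6 largest X-linked rises and 3 largest X-linked falls past the threshold with no overlap between groups, up to 4 members of each list, the 6 largest differences between mutants in each direction, and the 6 largest shared changes in each direction. Genes with clone names were passed over. The rule had no part for single genes with allelic reads: those named were chosen after their values were seen, as the 8 largest rises past the threshold with no overlap between groups, plus Nrk, Taf1, Ogt, Kdm5c and Xist. Hmgn5 and Ap1s2 were also named after their values were seen, as examples of the part of read depth. Pbdc1 and Zmym3 are examples of larger rises that were not called. Alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, quantile normalization, a fit over the 12 libraries, plain eBayes, the replicate number as a block, each library left out in turn, a minimum of 30 allelic reads and escapees left out. DESeq2 1.42.0, limma on the logit share, Xist alone left out, the Rhox genes left out and, for gene lists, no filter were added after seeing the data.

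The steps were tested on simulated data. Of genes changed by 1 on the log2 scale, limma recovered 70% in the Ring1 design (10697 genes) and 50% in the Eed design (10940 genes), and of those changed by 2 it recovered 97% and 85%. A share raised by 10 points was recovered for 83.3% of raised genes in the Ring1 design (122 genes) and 60% in the Eed design (132 genes). Simulated shares varied less between libraries than those of some real genes, such as Cenpi and Ofd1 in ΔEed (SD 23.7 and 14.5 points). For such genes these recoveries are too high.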

Results

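The question set by the series is whether Polycomb repressive complexes 1 and 2 are needed to keep the inactive X silent in extraembryonic tissue. In the mouse ectoplacental cone the paternal X is inactivated by imprinting, so reads from the paternal allele of X-linked genes measure loss of silencing. RNA was sequenced in 3 ΔRing1A/B libraries and 3 controls, and in 3 ΔEed libraries and 3 controls. Ring1A and Ring1B are the ubiquitin ligases at the core of PRC1, and Eed is a core subunit of PRC2, which methylates histone H3 at lysine 27. Allele-assigned reads ranged from 65337 to 173530 per library.

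The targeted genes were examined first. Ring1 (chromosome 17, 34157737 to 34161625, mm9), which encodes Ring1A and is mutated in all embryos of the Ring1 experiment, had a mean FPKM of 1.23 ± 0.201 in its controls and 1.58 ± 0.278 in ΔRing1A/B (SD, n = 3 each), against 5.55 ± 1.3 in the Eed controls and 5.72 ± 1.32 in ΔEed. Rnf2 (chromosome 1, 153316536 to 153347953), which encodes Ring1B, was at 32 ± 1.58 in the controls and 37.7 ± 1.69 in ΔRing1A/B, with a log2 change of 0.23 (SE 0.10, limma adjusted p = 0.0902). The Ring1B deletion removes part of the gene, and FPKM over the whole gene does not test for it. Eed (chromosome 7, 97103164 to 97129486) fell from 24.9 ± 0.696 to 16.4 ± 3.34 in ΔEed, a log2 change of -0.59 (SE 0.16, adjusted p = 0.0146), and all 3 mutant libraries lay below all 3 controls. In ΔRing1A/B, Eed was at 24.3 ± 1.29 against 22.1 ± 2.12 (adjusted p = 0.387).

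Reads from the paternal X rose in both mutants. With Xist left out, the paternal allele gave 2.64% ± 0.34 of X-linked allelic reads in the Ring1 controls and 10.3% ± 2.06 in ΔRing1A/B (SD, n = 3 each, exact permutation p = 0.1, the smallest that 3 against 3 allows). It gave 2.67% ± 0.283 in the Eed controls and 10.8% ± 2.04 in ΔEed (exact permutation p = 0.1). The lowest mutant library, at 7.97% (Wilson interval 7.8 to 8.14%), lay above the highest control, at 2.99% (2.85 to 3.13%). The number of genes with more than 10% paternal reads was between 5 and 7 of 121 in the Ring1 controls and between 19 and 45 in ΔRing1A/B. In the Eed experiment it was 6 or 7 of 131 in controls and between 13 and 43 in ΔEed. Xist, the RNA made by the inactive X itself (100655712 to 100678572 on X), came from the paternal allele in all groups, at 99.4% ± 0.166 and 99.5% ± 0.193 in the Ring1 experiment and 99.4% ± 0.182 and 99.4% ± 0.244 in the Eed experiment (SD, n = 3 each). With Xist kept, the paternal share was 12.6% ± 3.56 in the controls and 19.6% ± 4.49 in ΔRing1A/B (exact permutation p = 0.2, groups overlapping, a rise of 7.05 points that was 4.68 without ΔRing1A/B replicate 3), and 13.2% ± 1.47 and 19.4% ± 1.35 in the Eed experiment (exact permutation p = 0.1). Xist FPKM was 52.5 ± 18.5 and 60.6 ± 19.1 in the Ring1 experiment (adjusted p = 0.58).

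**Figure D1:**
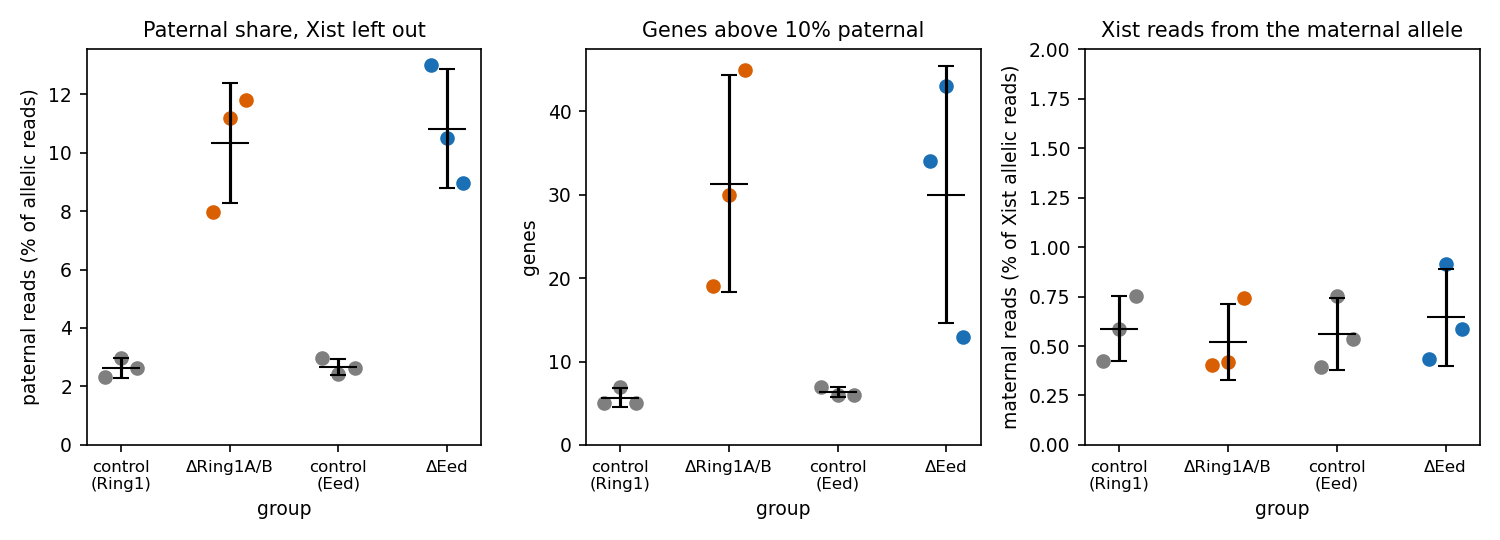
Each point is a library, grouped by genotype on the x axis with the mean and SD of 3, and the y axes are the paternal share of X-linked allelic reads in percent with Xist left out, the number of genes above 10% paternal reads, and the maternal share of Xist reads in percent. Paternal shares lie between 7.97% and 13% in the mutants and between 2.31% and 2.99% in the controls, and the maternal share of Xist stays below 1% in all libraries (highest 0.913%).

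In ΔRing1A/B, 37 of 122 genes rose in paternal share and 0 fell (edgeR adjusted p under 0.05, with 43 genes at an unadjusted p under 0.05). The largest rises were in Mbtps2, a protease that activates membrane-bound transcription factors, from 8.91% ± 4.89 to 40.7% ± 1.5, and Atrx, a chromatin remodeller (102992956 to 103124711), from 2.45% ± 1.14 to 32.6% ± 10.7 (SD, n = 3, edgeR adjusted p = 0.0444 and 0.000552). Hccs, Siah1b, Zrsr2, Zxdb, Cstf2 and Tmem29 followed among the genes called, with mutant means from 28.7% to 17.3%. In ΔEed, 19 of 132 genes rose and 0 fell (35 at an unadjusted p under 0.05). Among the 19 genes called, the largest rise was in Rlim, the X-linked ubiquitin ligase that promotes Xist expression (101152506 to 101176623). Its share went from 1.51% ± 0.388 to 22% ± 4.9 (SD, n = 3, edgeR adjusted p = 7.28e-26). Kif4, a mitotic kinesin, went from 0.276% ± 0.407 to 19.9% ± 1.01 (adjusted p = 0.000923). Some genes that were not called rose by more points than Rlim, such as Pbdc1 and Zmym3. Cenpi, Cstf2, Ofd1, Smc1a, Zfx and Med12 followed. The Cenpi share differed between ΔEed libraries, at 0.917%, 45.7% and 9.91%. Nrk, a kinase gene that holds many of the allelic reads, rose from 0.463% ± 0.0599 to 9.2% ± 0.732 in ΔRing1A/B and from 0.557% ± 0.0292 to 10.2% ± 2.95 in ΔEed (adjusted p = 1.09e-08 and 2.51e-35). Leaving out control replicate 3 or ΔRing1A/B replicate 2 left 24 or 23 genes in ΔRing1A/B. In ΔEed, leaving out control replicate 1 or mutant replicate 2 left 10 or 11, and DESeq2 called 40 and limma on the logit share 29.

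Some genes were already expressed from the paternal X in controls. Taf1, a subunit of the general transcription factor TFIID, had a paternal share of 43.7% ± 1.3 in the Ring1 controls and 49.6% ± 0.453 in ΔRing1A/B, and 43.5% ± 0.286 and 48.2% ± 8.36 in the Eed experiment (SD, n = 3, edgeR adjusted p = 0.739 and 0.986). Ogt, which adds sugar residues to nuclear proteins, was at 39% ± 1.67 and 44% ± 3.4 and at 41% ± 3.63 and 44.3% ± 0.597 (adjusted p = 0.739 and 0.994). The escapee Kdm5c was at 21.2% ± 1.22 and 32% ± 1.49 and at 21.1% ± 6.1 and 22.4% ± 3.96 (adjusted p = 0.408 and 1).

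Both mutants raised an overlapping set of genes. Of 118 genes tested in both, 16 rose in both, against 5.96 for independent lists (one-sided Fisher's exact p = 2.79e-07). Calls depend on read depth: in ΔRing1A/B, Hmgn5 (4583 reads or more) was called at a rise of 1.42 points. Ap1s2 (10 to 30 reads) was not called at 16.8 points. Nrk, Rlim and Hmgn5 hold the most reads in both experiments. Independent lists ignore such shared depth, so part of the overlap may come from it. A test of the difference between the mutants found 0 genes of 118 (edgeR, 3 at an unadjusted p under 0.05). This count does not show equal effects, since wide differences were not called either. Kif4 was at 2.65% ± 3.61 in ΔRing1A/B and 19.9% ± 1.01 in ΔEed, and Atrx at 32.6% ± 10.7 and 8.6% ± 2.92 (SD, n = 3, edgeR adjusted p = 0.989 for each). The rise in the paternal share, with Xist left out, differed by -0.51 percentage points between ΔRing1A/B and ΔEed over these genes (permutation p = 0.91 over 400 arrangements). That permutation exchanges genotype labels within experiments, so its null is no rise in either mutant. It cannot decide whether the rises are equal.

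**Figure D2:**
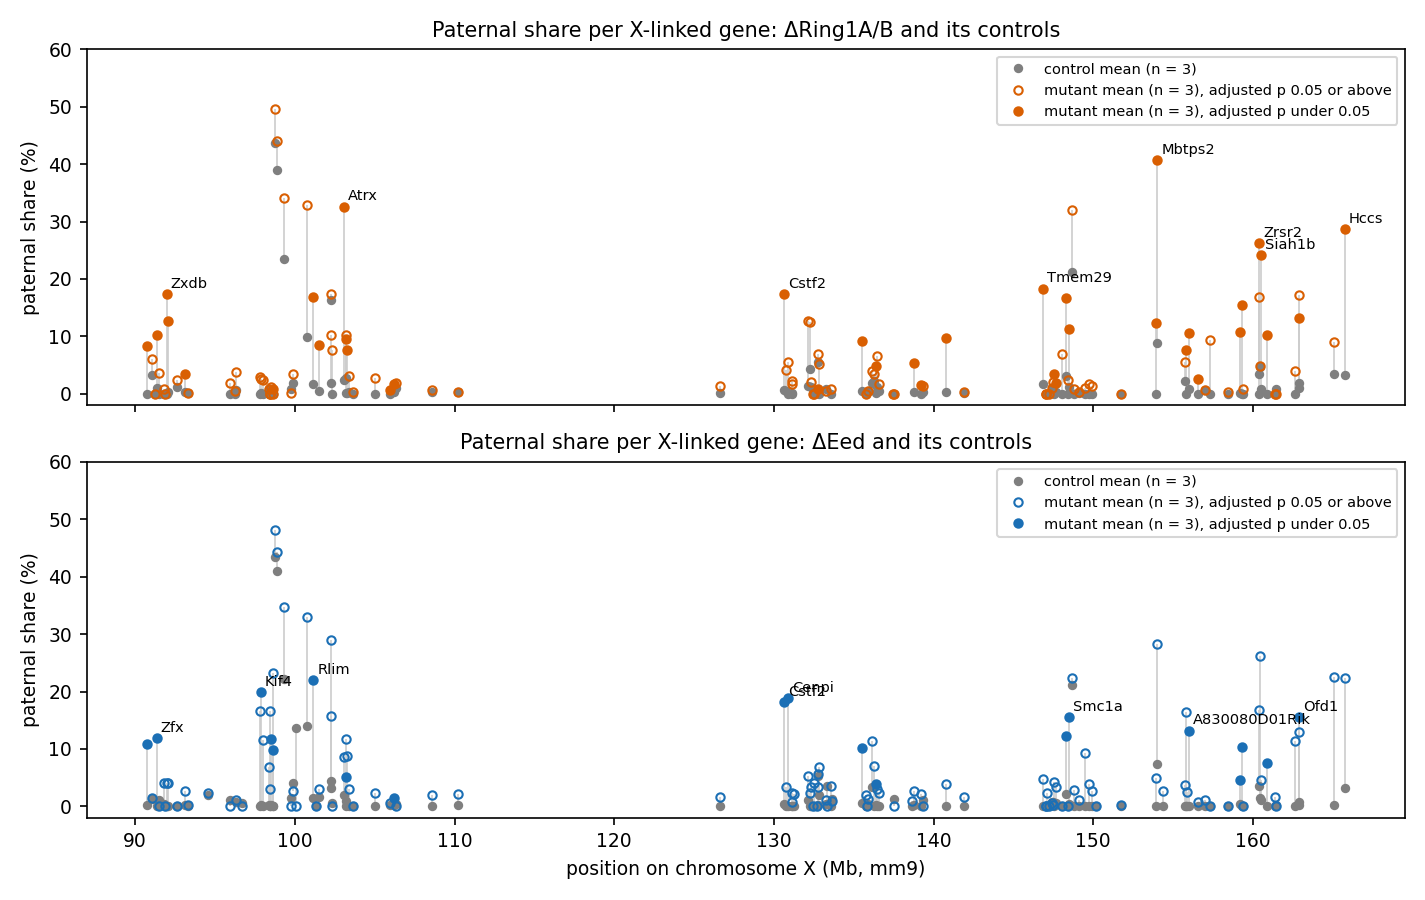
The x axis is the position on chromosome X in Mb (mm9) and the y axis the paternal share of allelic reads per gene in percent, Xist left out, with control means of 3 libraries in grey and mutant means in colour, filled where the edgeR adjusted p is under 0.05. Rises lie along the whole informative part, with Atrx at 32.6% in ΔRing1A/B and Rlim at 22% in ΔEed.

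X-linked expression as a whole rose relative to autosomes in ΔEed. The mean log2 change of 392 X-linked genes exceeded that of autosomal genes by 0.40 (camera p = 5.47e-05, and 0.0317 with an estimated correlation of 0.017), and 37.8% of X-linked genes rose against 24.3% of autosomal genes. Library means of X-linked minus autosomal log2 values went from -0.48 ± 0.02 to -0.08 ± 0.05 (SD, n = 3 each, exact permutation p = 0.1). In ΔRing1A/B the shift over 368 X-linked genes was 0.11 (camera p = 0.0236, and 0.134 with an estimated correlation of 0.0159), with library means from -0.33 ± 0.03 to -0.22 ± 0.03 (exact permutation p = 0.1). This camera call was also lost with no expression filter (0.05, p = 0.139), under quantile normalization (0.05, p = 0.167) and without ΔRing1A/B replicate 2 (0.0931, p = 0.0551), and the exact test above cannot reach 0.05 in this design. Against 10000 autosomal lists matched on expression, the X-linked mean change in ΔRing1A/B (0.197) was at percentile 93.06, with a matched mean of 0.15 and a highest of 0.264. The X-linked median (0.108, against -0.0493 for autosomal genes) was above those of all 10000 random autosomal lists of the same size, which were not matched. The log2 change was positive for 60.1% of X-linked and 45.5% of autosomal genes. In ΔEed the X-linked mean (0.545) was above all matched lists (matched mean 0.225, highest 0.426). Its median (0.317, against -0.0501) was also above those of all unmatched lists, with 67.1% and 46.7% of genes positive. Without the 20 X-linked genes that rose most, a removal that lowers any shift, the shifts were 0.0099 in ΔRing1A/B and 0.243 in ΔEed. The shifts of both mutants differed by -0.29 (ΔRing1A/B minus ΔEed, 387 genes, camera p = 0.000158, and 0.0132 with an estimated correlation). An exact permutation of genotype labels within experiments gave p = 0.1. Its null is no shift in either mutant, so it does not test whether the shifts differ.

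**Figure D3:**
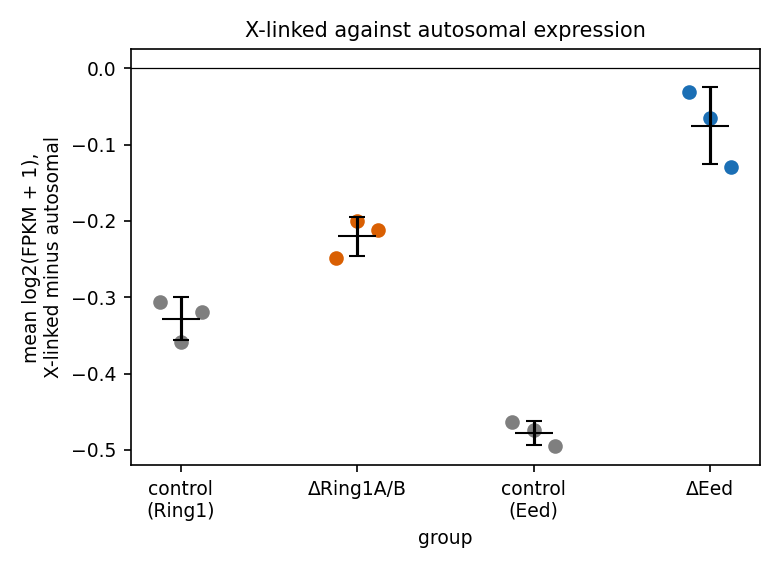
Each point is a library, grouped by genotype on the x axis, and the y axis is the mean log2(FPKM + 1) of X-linked genes minus that of autosomal genes, with the mean and SD of 3 libraries. The ΔEed libraries average -0.08 and their controls -0.48, and the ΔRing1A/B libraries average -0.22 and their controls -0.33.

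In ΔRing1A/B, Pitx1, a homeobox factor of hindlimb and pituitary (chromosome 13, 55926415 to 55932786), rose from 0.575 ± 0.0839 to 20 ± 1.64 FPKM (SD, n = 3 each), a log2 change of 3.73 (SE 0.15, adjusted p = 6.49e-07). Tcf15, a factor of paraxial mesoderm, rose by 3.75 (SE 0.17), and Barx1, a homeobox factor of stomach and craniofacial mesenchyme, by 3.55 (SE 0.17). The largest autosomal rise was that of Trp53i11 (chromosome 2, 93027741 to 93041914), from 0.704 ± 0.389 to 32 ± 5.99 FPKM, a log2 change of 4.28 (SE 0.20, adjusted p = 7.85e-07). Ppp2r2c, Crip2, Dbn1 and Rarres2 rose by 3.42, 3.41, 3.35 and 3.28. Among X-linked genes Esx1, a placental homeobox gene (133649936 to 133654865), rose from 0.862 ± 0.3 to 22.9 ± 0.279 FPKM, a log2 change of 3.70 (SE 0.16, adjusted p = 6.49e-07), and Rhox9, Rhox6, Efnb1, Dmrtc1b and Tsc22d3 by 2.72, 2.39, 1.96, 1.95 and 1.87. The largest falls were in Prl4a1, a prolactin family gene, from 83.6 ± 47 to 3.51 ± 2.83 (log2 change -4.34, SE 0.91, adjusted p = 0.0235), and Adm, which encodes the peptide adrenomedullin, from 313 ± 34.2 to 34.4 ± 7.71 (log2 change -3.17, SE 0.16). Nfkbiz, Fasl, Id1, Card9, Cd47 and Cdk20 fell by 2.42, 2.37, 2.32, 2.15, 2.10 and 2.00 on the log2 scale, and the X-linked genes Tceal8, Was and Amot fell by 1.16, 1.07 and 1.06. In all, 2107 genes rose and 1919 fell of 10697 tested (limma, adjusted p under 0.05), and 1004 of the rises and 149 of the falls were at least 1 on the log2 scale. Under quantile normalization 1831 rose and 1932 fell. Without control replicate 3 the falls numbered 1248. The groups did not overlap for 50.6% of tested genes, where chance gives 10%.

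Among the fixed lists in ΔRing1A/B, 8 of 23 passed camera at the preset correlation, and 0 with an estimated one (2 at an unadjusted p under 0.05). Fry called 14 lists, and 14 of 25 without the expression filter. A gene low in the controls passes the filter only if the mutant is high, and the reverse holds for a gene low in the mutant. Counts without the filter therefore follow for lists mostly below it. Of 90 developmental regulators bound by Polycomb 22 were tested, and 16 rose and 3 fell, the same counts when adjusted over the list alone, but 15 of the 16 were under 1 FPKM in the controls. They included Six2 from 0.748 ± 0.483 to 14.6 ± 1.68 FPKM and Lhx2 and Six3, up by 2.29 and 2.18 (camera adjusted p = 0.000141, and adjusted p = 0.183 with an estimated correlation). Without the filter 47 of 81 rose and 3 fell (camera adjusted p = 2.33e-11, and 0.0932 with an estimated correlation). Of 39 Hox genes 3 were tested, all under 1 FPKM in the controls, so the filter selected them by their rise, with Hoxb13 up by 2.06 (SE 0.22) and Hoxd13 by 1.79 (adjusted p = 0.0115, and 0.372 with an estimated correlation). Without the filter 13 of 31 rose and 0 fell (camera adjusted p = 2.8e-05, and 0.498 with an estimated correlation). Germline genes rose in 10 (7 of them under 1 FPKM in the controls) and fell in 1 of 16, also over the list alone, and in 14 and 1 of 28 without the filter, with the RNA helicase gene Ddx4 up by 2.76 (SE 0.22) and Tdrkh by 2.41 (adjusted p = 0.00028, and 0.183 with an estimated correlation). PRC1 subunits rose in 14 and fell in 3 of 24 (16 and 4 adjusted over the list alone), with Cbx4, Bcorl1, Cbx6 and E2f6 up by 1.71, 1.69, 1.43 and 1.41 (adjusted p = 0.000683, and 0.372 with an estimated correlation). Cell cycle inhibitors and p53 targets rose in 7 and fell in 1 of 15, also over the list alone, with the proapoptotic gene Pmaip1 up by 2.50 and the CDK inhibitor Cdkn1a by 1.72 (adjusted p = 0.0115, and 0.395 with an estimated correlation). Other imprinted genes rose in 11 and fell in 2 of 16, also over the list alone, with Zim1 up by 1.45 and Gnas by 1.29 (adjusted p = 0.00494, and 0.563 with an estimated correlation). Of 11 endothelium markers 4 were tested, and all 4 fell, also over the list alone, with Pecam1, Esam, Kdr and Cdh5 down (adjusted p = 0.00399, and 0.469 with an estimated correlation). Without the filter 4 of 11 fell and 0 rose (camera adjusted p = 0.0197, and 0.498 with an estimated correlation). Proliferation genes fell in 9 of 20 and rose in 0 (10 falls over the list alone), with Rrm2, a subunit of the enzyme that makes deoxynucleotides, from 251 ± 43.9 to 119 ± 9.65 FPKM (adjusted p = 0.00443, and 0.563 with an estimated correlation). Under quantile normalization 4 of the 20 fell and 1 rose, and the median went from -0.30 to -0.15.

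The remaining lists did not pass camera in ΔRing1A/B. The trophoblast stem and extraembryonic ectoderm list split, with 6 of 12 up and 4 down: Eomes, a factor of trophoblast stem cells, rose from 0.587 ± 0.241 to 10.4 ± 1.46 FPKM and Wnt7b from 1.02 ± 0.331 to 18.4 ± 6.96. Giant cell genes rose in 1 and fell in 3 of 14 (0 and 2 over the list alone), including Hand1, a factor needed for giant cells, from 739 ± 54.1 to 310 ± 62.6. Ectoplacental cone and spongiotrophoblast genes rose in 4 and fell in 3 of 12, with Plet1 from 465 ± 21.1 to 209 ± 38.8. Labyrinth genes rose in 5 and fell in 2 of 10, with Cebpa up by 1.99. Decidua markers rose in 2 and fell in 1 of 8, with Wnt4 up by 3.10. Erythroid genes rose in 1 and fell in 2 of 5, endoderm genes rose in 1 and fell in 1 of 8, and the pair of epiblast genes tested split, with Utf1 up by 0.42 and Dnmt3b changed by -0.39. Cd68 was the 1 leukocyte gene tested and did not pass (adjusted p = 0.329). PRC2 subunits rose in 2 and fell in 1 of 12, with Suz12 changed by -0.57, the X inactivation centre in 0 of 3, known escapees in 1 up and 1 down of 8, X-linked housekeeping genes in 3 up and 2 down of 19 (0 and 0 over the list alone), and the Rhox cluster in 3 up and 1 down of 10. Under quantile normalization the median turned from 0.23 to -0.19 for the Rhox list, from 0.10 to -0.43 for decidua, from 0.01 to -0.47 for erythroid genes, from -0.08 to 0.05 for X-linked housekeeping genes and from -0.01 to 0.10 for PRC2 subunits, and the Cd68 change from 0.32 to -0.26. The erythroid median was above 0 while its mean (-0.25) and camera were negative, and the PRC2 median was below 0 while its mean (0.01) and camera were positive. H3K27me3-dependent imprinted genes rose in 2 of 5, and genes of the Kcnq1ot1 and Airn domains rose in 3 and fell in 1 of 12, with the CDK inhibitor Cdkn1c up by 0.94. Stress genes rose in 2 and fell in 3 of 12 (2 and 4 over the list alone). No Y-linked gene is in the table.

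In ΔEed, the X-linked homeobox gene Rhox9 (35252274 to 35254947 on X) rose from 33.5 ± 27.7 to 1760 ± 249 FPKM, a log2 change of 6.07 (SE 0.59, adjusted p = 0.000168), and Rhox6 from 69.4 ± 46.4 to 1740 ± 287 (SD, n = 3 each). Rhox12 rose from 0.166 ± 0.144 to 40.2 ± 23, and Gpr50, Arhgef6 and Itm2a rose by 4.93, 4.36 and 3.89 on the log2 scale. Gjb2, a gap junction protein (chromosome 14, 57717439 to 57723539), rose from 0.772 ± 1.34 to 139 ± 70.9 FPKM, a log2 change of 6.44 (SE 0.50, adjusted p = 7.35e-05). Cyp11a1, the enzyme that begins steroid hormone synthesis, rose from 0.248 ± 0.335 to 40 ± 24.3, and Rarres2, Muc1, Fbln2, Plat, Islr2 and Isg15 by 5.49, 5.37, 4.98, 4.93, 4.86 and 4.81. The largest fall was in Card9, a signalling adaptor (chromosome 2, 26207832 to 26215067), from 28.8 ± 4.38 to 1.17 ± 0.516 FPKM (log2 change -3.80, SE 0.22, adjusted p = 3.16e-05). Ccdc27, Rab26os, Amd1, Id1, Mif4gd, Itgb4 and Ppp1r3b fell by 3.29, 2.95, 2.79, 2.78, 2.56, 2.48 and 2.27 on the log2 scale. Among X-linked genes Dkc1, a ribosomal RNA modification and telomerase protein, went from 58 ± 5.57 to 19.1 ± 4.14 FPKM, and Zfp280c and Eif1ax fell by 1.24 and 1.15. In all, 2709 genes rose and 2586 fell of 10940 tested (limma, adjusted p under 0.05), with 1664 and 521 at least 1 on the log2 scale. Under quantile normalization the balance turned, with 2027 rises and 2702 falls. Without control replicate 2 the falls numbered 1709. The groups did not overlap for 59% of genes, where chance gives 10%.

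Among the fixed lists in ΔEed, 7 of 23 passed camera at the preset correlation, and 0 with an estimated one (4 at an unadjusted p under 0.05). Fry called 17 lists, and 18 of 25 without the expression filter. Proliferation genes fell in 18 of 20 and rose in 0 (19 over the list alone), with Rrm2 from 276 ± 32.6 to 103 ± 14.8 FPKM and Birc5 from 243 ± 11.3 to 125 ± 4.47 (camera adjusted p = 2.42e-05, and 0.136 with an estimated correlation). Under quantile normalization 10 of the 20 fell. Germline genes rose in 13 of 21 (11 of them under 1 FPKM in the controls) and fell in 0 (15 over the list alone), and rose in 14 of 28 without the filter, with the synaptonemal complex gene Sycp1 up by 3.39 (adjusted p = 6.84e-05, and 0.116 with an estimated correlation). Other imprinted genes rose in 13 and fell in 1 of 18 (15 and 1 over the list alone), with Plagl1, Ndn, Sgce and Meg3 up by 2.73, 2.66, 2.07 and 2.05 (adjusted p = 6.84e-05, and 0.116 with an estimated correlation). Cell cycle inhibitors and p53 targets rose in 8 of 16 and fell in 0, also over the list alone, with Cdkn1a from 1.72 ± 0.668 to 20.7 ± 4.22 FPKM (adjusted p = 0.0035, and 0.136 with an estimated correlation). Giant cell genes rose in 9 of 17 (6 of them under 1 FPKM in the controls) and fell in 0, also over the list alone, and rose in 6 of 21 without the filter, with Bhlhe40 up by 4.09, Serpinb9d by 3.82 and Prl2c3 by 3.32 (adjusted p = 0.00396, and 0.445 with an estimated correlation). Prl2c3 has near-identical relatives, and how shared reads were assigned is not given. Labyrinth genes rose in 7 and fell in 1 of 10, also over the list alone, with Syna, which encodes syncytin-A, from 2.06 ± 3.44 to 47.8 ± 24.6 FPKM and Hsd11b2 up by 4.48 (adjusted p = 0.00396, and 0.445 with an estimated correlation). Of 21 endoderm genes 7 were tested and rose, also over the list alone, 4 of them from under 1 FPKM in the controls, with the basement membrane genes Col4a1, Sparc and Lama1 up by 3.94, 2.88 and 2.09 (adjusted p = 0.0035, and 0.445 with an estimated correlation), and 3 rose under quantile normalization. Without the filter 5 of 20 rose and 0 fell (camera adjusted p = 0.00919, and 0.478 with an estimated correlation).

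The other lists did not pass camera in ΔEed. Of 90 developmental regulators bound by Polycomb 14 were tested, and 9 rose (7 from under 1 FPKM in the controls) and 2 fell, also over the list alone, with Pitx1 up by 3.22, Six2 by 2.74 and Lhx2 by 2.34 (adjusted p = 0.0512), and 4 rose under quantile normalization. Without the filter 24 of 79 rose and 2 fell (camera adjusted p = 0.000401, and 0.244 with an estimated correlation). Of 39 Hox genes 2 were tested, both under 1 FPKM in the controls and so selected by their rise, Hoxb13 from a listed 0 in the controls to 3.41 ± 2.31 FPKM and Hoxa1 by 1.10. Without the filter 5 of 24 rose and 0 fell (camera adjusted p = 0.0484, and 0.244 with an estimated correlation). PRC1 subunits rose in 11 and fell in 4 of 24 (11 and 5 over the list alone), with Cbx4 from 0.985 ± 0.449 to 8.12 ± 1.84 FPKM, Phc1 up by 2.02 and Bmi1 by 1.21. PRC2 subunits rose in 2 and fell in 4 of 12, with Suz12 changed by -0.76. H3K27me3-dependent imprinted genes rose in 3 of 5, Smoc1 by 1.06, Sfmbt2 by 0.68 and Jade1 by 0.58. Genes of the Kcnq1ot1 and Airn domains rose in 6 and fell in 2 of 13, with Cdkn1c from 674 ± 87.3 to 2450 ± 311 FPKM and Phlda2 from 863 ± 161 to 272 ± 179. Trophoblast stem genes rose in 5 and fell in 4 of 12, and ectoplacental cone genes rose in 5 and fell in 3 of 12 (5 and 4 over the list alone). The X inactivation centre had 1 rise and 1 fall among 5, known escapees 2 and 2 among 10 (1 and 1 over the list alone), X-linked housekeeping genes 6 and 1 among 19, and the Rhox cluster 3 and 2 among 13 (3 and 1 over the list alone). Under quantile normalization the median turned from 0.29 to -0.27 for the Rhox list, from 0.15 to -0.33 for erythroid genes, from 0.34 to -0.16 for leukocyte genes and from -0.03 to 0.10 for trophoblast stem genes. The trophoblast stem median and camera were negative while the mean was 0.16, and the escapee median (-0.10) and camera were negative while the mean was 0.00396. Decidua markers rose in 2 and fell in 1 of 5 (3 and 1 over the list alone), erythroid genes rose in 1 of 3, leukocyte genes in 1 of 3 (Csf1r, by 3.01), and endothelium markers in 1 up and 1 down of 4 (2 and 1 over the list alone). The pair of epiblast genes tested fell, Dnmt3b by 1.64 and Utf1 by 0.96. Stress genes rose in 5 and fell in 2 of 12, with Jun up by 2.15 and Ier2 changed by -2.05.

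**Figure D4:**
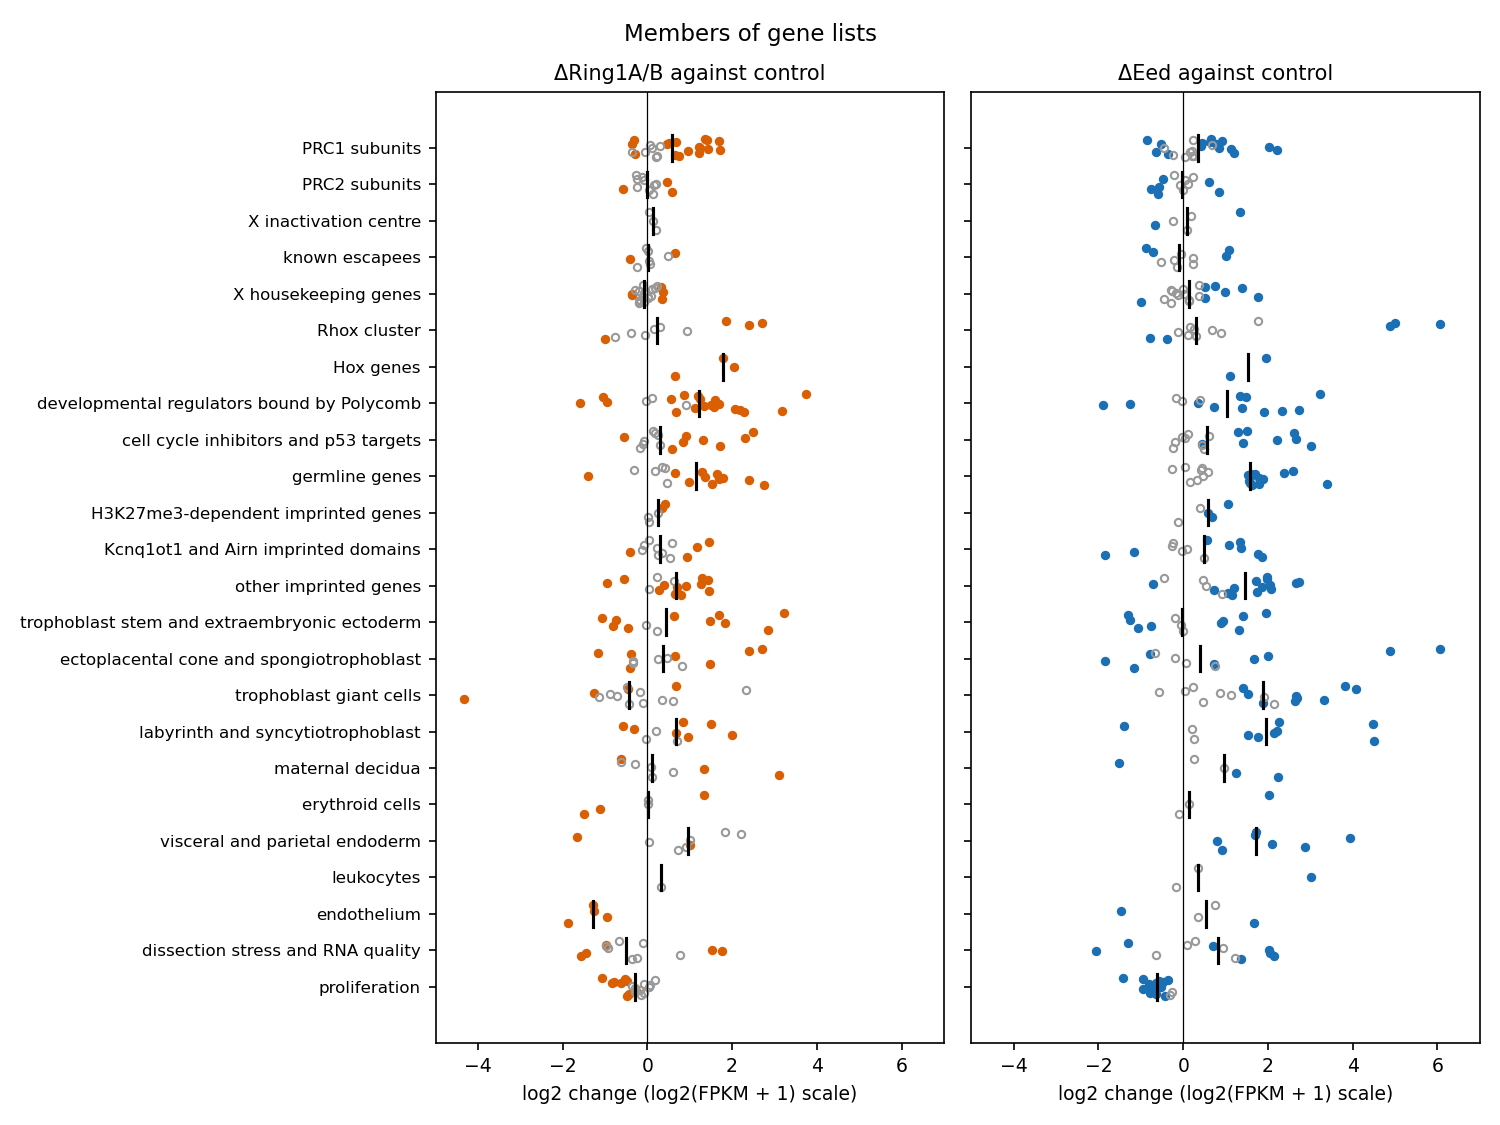
The x axis is the log2 change of each tested list member against its own controls, on the log2(FPKM + 1) scale, with ΔRing1A/B in the left panel and ΔEed in the right, points filled where the limma adjusted p is under 0.05, and black bars at list medians. The tested developmental regulators have a median of 1.22 in ΔRing1A/B and 1.04 in ΔEed, and proliferation genes of -0.30 and -0.63. Most of these regulators that rose were under 1 FPKM in the controls, and without the expression filter the regulator medians are 0.425 and 0.341.

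The same genes changed in both mutants more often than independent lists would give. Of 10425 genes tested in both, 1410 rose in both, against 445 for independent lists, and 1138 fell in both, against 473 (one-sided Fisher's exact p = 3.81e-293 for the falls and below the smallest number the software holds for the rises). The Fisher p-values take genes as independent and do not measure the spread between libraries. Calls in both experiments can also depend on expression level, so part of the overlap may come from it. In all 2548 of 2614 genes called in both moved the same way, and 66 moved in opposite directions. Trp53i11, Rhox9, Rarres2, Isg15, Parp12 and Muc1 had the largest mean shared rises, and Card9, Id1, Ccdc27, Nfkbiz, Fasl and Mif4gd the largest shared falls. Parp12, an antiviral ADP-ribosyltransferase, rose from 2 ± 0.867 to 22.9 ± 3.26 FPKM in ΔRing1A/B and from 0.497 ± 0.358 to 33 ± 7.79 in ΔEed.

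The interaction test found 1505 of 10868 genes whose effects differed, 692 higher in ΔRing1A/B and 813 higher in ΔEed (927 and 804 under quantile normalization). Higher means the more positive log2 change, not the larger change in size. Leaving out 1 of 6 single libraries (Ring1 controls 1 and 2, ΔRing1A/B 1 and 2, Eed controls 2 and 3) brought the count to between 836 and 1002. Ddah1, Rab26os, B4galnt1, Hmx1, Hmga2 and H2afy2 had the largest difference towards ΔRing1A/B. Ddah1, on the trophoblast stem list, went from 4.14 ± 0.974 to 15.4 ± 1.46 FPKM in ΔRing1A/B and from 6.86 ± 0.804 to 2.2 ± 0.457 in ΔEed (interaction 2.99, SE 0.24, limma adjusted p = 6.26e-05). Hmga2, a chromatin protein of embryonic growth, went from 12.8 ± 1.02 to 27.3 ± 4.71 and from 14.6 ± 1.18 to 4.59 ± 0.81 (interaction 2.52). Prl4a1, Gjb2, Rpl10l, Adamts1, Ghrh and Prl2a1 had the largest difference towards ΔEed. Prl4a1 went from 83.6 ± 47 to 3.51 ± 2.83 in ΔRing1A/B and from 12.3 ± 16.2 to 39 ± 32.6 in ΔEed (interaction -6.25, SE 1.73, adjusted p = 0.0431). Ghrh, the growth hormone releasing hormone gene, is listed at 0 in all controls and averaged 35.5 FPKM in ΔEed. The mutants were made at different times and sequenced on different platforms, so these differences are between experiments.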

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

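In this part, the tests on maternal Xist reads, of a few strongly raised genes and of visceral, parietal and decidual genes, and the splits of the libraries for FPKM, were chosen only after the result was seen.

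The effects of the mutants, each against its own controls, differed for 692 genes with a higher effect in ΔRing1A/B and 813 with a higher effect in ΔEed (limma interaction, adjusted p under 0.05), and the X-linked shift differed by -0.29. Of 100 splits of the libraries within experiments, 8 gave as many genes as the 1505 found (highest other 6365). The splits that call more exchange or mix the genotype labels of one experiment, which turns the difference of similar effects into their sum or exposes one effect, a structure of the samples, so these counts decide nothing on chance. The differences below are log2 changes in ΔRing1A/B minus those in ΔEed, and experiment and genotype are not separable in them. A higher effect is the more positive log2 change, not the larger change in size. Among genes on the ΔEed side, Prl4a1, Adm, Cd47, Tceal8, Pecam1, Esam and Cdh5 fell in ΔRing1A/B.

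Genes with a higher effect in ΔRing1A/B included Ddah1 (2.99), B4galnt1 (2.7), Hmga2 (2.52) and H2afy2 (2.51). Hmx1, listed at 0 in the Ring1 controls, had a fitted difference of 2.62. Rab26os (2.76), Ppp1r3b (2.09), Ccdc27 (1.68), Card9 (1.65), Itgb4 (1.53) and Mif4gd (1.19) were among the largest falls of ΔEed. The list members Phlda2 (2.1), Eomes (1.53), Utf1 (1.37), Dnmt3b (1.25), Six3 (0.79), Tdrd1 (1.36), Ddx4 (1.14), E2f6 (1.18), Mcm6 (0.74) and Bub1 (0.66), the target Eed (0.72), and the X-linked genes Zfp280c (1.56), Pgk1 (0.91), Utp14a (0.84) and Bcorl1 (0.78) also lay on this side.

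Genes with a higher effect in ΔEed included the autosomal genes Prl4a1 (-6.25), Prl2a1 (-4.1), Prl2c3 (-2.88), Prl2c5 (-2.35), Cyp11a1 (-4.06), Adamts1 (-4.22), Adm (-2.56), Plat (-3.74), Fbln2 (-3.59) and Serpinb9d (-3.13). Ghrh, listed at 0 in all controls, had a fitted difference of -4.11. The autosomal genes Gjb2 (-5.14), Syna (-3.8), Muc1 (-3.22), Hsd11b2 (-2.99), Cd47 (-2.59), Islr2 (-2.38), Epha4 (-2.02), Lifr (-1.87), Fzd5 (-1.42) and Ncam1 (-1.36) also lay on this side. X-linked genes were Gpr50 (-3.59), Rhox9 (-3.35), Itm2a (-3.15), Rhox12 (-3.14), Arhgef6 (-3.01), Rhox6 (-2.48), Lamp2 (-1.75), Tceal8 (-1.64), Atp6ap2 (-1.2) and Usp9x (-0.62). The list members Pecam1 (-3.55), Thbd (-2.46), Csf1r (-2.21), Esam (-2.04), Cdh5 (-1.31), Plagl1 (-2.59), Ndn (-2.03), Sgce (-2.03), Cdkn1c (-0.92), Sfmbt2 (-0.67) and Smoc1 (-0.65), and Rpl10l (-4.86), Tuba3b (-2.44), Jun (-2.39), Sycp1 (-1.86), Parp12 (-1.47), Cdkn1a (-1.29), Trp53inp1 (-0.91) and Phc1 (-0.81) made up the rest.

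Paternal reads from the X rose by 7.68 and 8.13 percentage points with Xist left out. Cells with random inactivation would bring Xist from the maternal allele, but its share rose by at most 0.0845 points, and the highest control had 0.754%, which argues against such cells and against maternal tissue diluting the controls. Without the 10 genes with the most reads, 63.3% and 64.4% of the total, the rise was still at least 5.09 points, which argues against a few genes as the whole source. Loss of silencing by the deletions is a candidate explanation, found and tested on the same data. The variant list and aligner are not given, so their part was not tested, and the splits (37 and 19 genes, highest other 0) are too few, at 10, for a share under 0.05.

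X-linked FPKM rose in ΔEed by more than the autosomal mean. The X-linked median was 0.317 against -0.0501 for autosomes, which argues against a few strongly raised genes as the whole cause, and the highest of 10000 autosomal lists matched on expression had a mean of 0.426 against 0.545, which argues against expression level. Whether paternal reads are the whole source was tested on 127 genes with allelic reads, where the maternal allele changed by 0.0479 (SE 0.0797) relative to autosomes and the total by 0.125 (SE 0.0781). These genes have 10 or more allelic reads in each library, a filter that leaves out genes near 0 in the controls. Summed over them, FPKM from the maternal allele rose from 5830 ± 108 to 6610 ± 224 and from the paternal allele from 111 ± 10.8 to 485 ± 126 (SD, n = 3). In thousandths of the summed autosomal FPKM the maternal sum went from 13.1 ± 0.0216 to 15.9 ± 0.963, so paternal reads are not the whole rise of FPKM summed over both alleles, a sum that genes with high FPKM dominate. Without the 3 genes that rose most on each allele, a removal that lowers any change, the maternal sum changed by -22.9 FPKM and the paternal sum by 216. The removal takes out risers alone, and these 2 changes are not scaled to the autosomal sum. It therefore cannot tell whether the maternal rise is general. The median maternal log2 change over the 127 genes was 0.0865 above the autosomal median. For the mean log2 shift the source stays open.

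All 7 endoderm genes tested, of 21 in the table, rose in ΔEed, and 5 of 20 without the expression filter. Of the 7, 3 were past the threshold under quantile normalization. The abundant visceral endoderm transcripts had a median of 0.117 FPKM (Afp at 0, Rbp4 at 0.274) and stromal transcripts of the decidua one of 0.389. This argues against visceral endoderm or decidual stroma as the main source. Of the stromal transcripts, Col1a2 went from 0.0069 to 1.08 FPKM and Col1a1 from 0.145 to 0.655. Col3a1 went from 0.634 to 0.389, and Dcn and Lum stayed at 0. Without the filter, decidua markers rose in 4 and fell in 1 of 15, so a small decidual part stays open. Parietal endoderm cells stay open, since all 5 of their genes rose and trophoblast giant cells express several of them. A change within trophoblast was not tested.

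The other splits gave these counts. Genes changed numbered 4026 and 5295 (highest other 0 in each) and lists past camera 8 and 7 (highest other 8 and 7), where 10 splits are too few for a share under 0.05. For the 2548 calls shared in direction, 1 of 100 splits, the real one, was as large. The highest other, 66, exchanges the labels of the Eed experiment and so counts the opposite calls, and the rest share 0, since any mixed grouping of an experiment calls 0 genes there. This count does not test the overlap. For the paternal share, the difference between mutants gave 0 genes, a count that all 100 splits reach by construction (highest other 47), so this decides nothing.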

How the results depend on the processing

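DESeq2, limma on the logit share, Xist alone left out, the Rhox genes left out and lists with no filter were added after seeing the data. Shifts, shares, total counts of genes and counts of lists not given here kept their direction and their side of the threshold, or a count within 1.5 times, under the alternatives run. The X-linked shift in ΔRing1A/B lost its call with no filter (0.0512, p = 0.139), under quantile normalization (0.053, p = 0.167) and with an estimated correlation (0.108, p = 0.134). With an estimated correlation 0 lists passed in ΔRing1A/B and 0 in ΔEed, and with no filter 8 and 9, against 8 and 7. Genes with a changed paternal share in ΔEed numbered 40 by DESeq2 and 29 by limma on the logit share, against 19. The rise in ΔEed was 8.16 points with escapees and Xist left out and 8.13 with Xist alone left out, against 6.21. Under quantile normalization, genes past the threshold numbered 1831 higher and 1932 lower in ΔRing1A/B (against 2107 and 1919), 2027 and 2702 in ΔEed (against 2709 and 2586), and 927 and 804 for the difference (against 692 and 813), so the larger side changed in each. Within lists it left 4 proliferation falls in ΔRing1A/B (against 9, with 1 rise) and 10 in ΔEed (against 18), and in ΔEed 4 rises of developmental regulators (against 9), 3 of endoderm genes (against 7) and 2 of trophoblast stem genes (against 5). In ΔRing1A/B, falls went from 1 to 3 in the Rhox cluster, 3 to 5 in giant cell genes and 3 to 0 in PRC1 subunits, and other list counts of 5 or fewer moved by at most 2. Without Rhox genes the X-linked shifts were 0.0963 and 0.371. For these changes the cause was not tested.

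Leaving out each library in turn gave 3006 to 3750 changed genes in ΔRing1A/B (higher 1660 to 1997, lower 1248 to 1753, with 1248 without control replicate 3) and 3884 to 5228 in ΔEed (higher 2175 to 2637, lower 1709 to 2591, with 1709 without control replicate 2). Genes whose effects differ ranged from 836 to 1880 (312 to 885 higher in ΔRing1A/B, 524 to 995 higher in ΔEed), with 1002 without Ring1 control 1, 930 without control 2, 921 without ΔRing1A/B 1, 954 without ΔRing1A/B 2, 836 without Eed control 2 and 953 without Eed control 3. The X-linked shift ranged from 0.089 to 0.122 in ΔRing1A/B (0.0931 without ΔRing1A/B replicate 2, where the camera call was lost), from 0.391 to 0.44 in ΔEed, and their difference from -0.314 to -0.259. Genes with a changed paternal share ranged from 23 to 40 in ΔRing1A/B (24 without control 3, 23 without ΔRing1A/B 2) and from 10 to 17 in ΔEed (10 without control 1, 11 without ΔEed 2), and the rise with Xist kept from 4.68 to 9.16 (4.68 without ΔRing1A/B 3) and from 5.44 to 6.98 points.

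Replicate numbers did not pair the libraries (correlations of deviations from -0.132 to 0.165). With the number as a replicate block, 3636, 5360 and 1188 genes were called in ΔRing1A/B, in ΔEed and for the difference. Of 2806 values of 231 named gene results under alternatives, 2627 kept their side of the threshold, 176 lost their call (107 on leaving out a library), 3 gained one and 0 reversed. Depth limits the allelic tests to genes with 10 reads in each library, and the depth behind FPKM is unknown.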

Other observations

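The interferon list and the comparison of rises between mutants were tested only after the result was seen. Of 48 interferon-stimulated genes, 36 of 38 tested rose in ΔRing1A/B and 35 of 37 in ΔEed, with 0 falls and median log2 changes of 1.69 and 2.53. Of the rises, 13 and 22 were from under 1 FPKM in the controls and so passed the expression filter through the mutant. Without the filter 40 and 38 of 48 rose and 0 fell. Bst2, a membrane protein that holds back viruses, went from 41.6 ± 12.2 to 137 ± 15.8 FPKM in ΔRing1A/B, and Stat1, the transcription factor of the pathway, from 12.6 ± 1.22 to 50.6 ± 10.3 in ΔEed (SD, n = 3). Fry, which asks whether the members move one way, gave p-values of 0.000592 and 0.000573 over all 48 without the filter, so the set moved up in both mutants. Against other genes, camera gave p-values of 7.48e-19 and 4.73e-18 at the preset correlation and 0.0612 and 0.0901 with an estimated correlation (1.45e-15, 5.54e-16, 0.062 and 0.0967 without the filter). Of all genes tested, 2107 of 10697 and 2709 of 10940 rose, with median log2 changes of -0.0448 and -0.0391, so the members rose more often than other genes. Whether this exceeds what a set of correlated genes can give stays open at the estimated correlation, and the source of the rise was not tested.

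Across genes, which are not independent replicates, 5 relations of the rise in paternal share were computed. The rise was not related to distance from Xist (Spearman 0.0976 and 0.0282, permutation p = 0.288 and 0.749, adjusted p = 0.36 and 0.749). The rises in both mutants correlated over 117 genes (Spearman 0.518, Pearson 0.444, permutation p = 1e-05, the smallest that the permutations can give, adjusted p = 5e-05). Genes with a higher paternal share in the controls of the other experiment rose more in ΔRing1A/B and in ΔEed (Spearman 0.303 and 0.255, Pearson 0.171 and 0.102, permutation p = 0.00092 and 0.00559, adjusted p = 0.0023 and 0.00932). Read depth was not adjusted for in these relations. Genes with few reads can sit at 0 in controls and mutants alike, so part of the correlations may come from depth. That residual paternal expression marks genes that respond more is a hypothesis from the same data.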
